A study of Saccharomyces cerevisiae with 270 samples.

How the data were processed

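RNA of yeast strains (Saccharomyces cerevisiae) that overexpress or lack a transcription factor was hybridised with the RNA of a control strain to spotted arrays of 2 colours, per the labels. The labels put 270 arrays into 135 groups of 2: 76 overexpression strains, 51 deletion strains and 8 points of a GCN4 series. Overexpression strains and the GCN4 series were compared with a strain carrying the empty vector, and deletion strains with the wild type, so the kind of strain and the kind of control cannot be told apart. In each group replicate 1 has the mutant in Cy5 and replicate 2 has it in Cy3, per the labels, so the replicate number is also the dye orientation. The labels do not say whether both arrays of a pair hold the same extracts, nor whether the control RNA was a common pool. The p-values of genes within a strain therefore measure only the spread between these arrays, which may be technical. Tests over strains, factors or points of the series compare values of whole strains or points, each from 2 arrays. The number of arrays per strain, 2, limits the precision of every value.

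Each array file gives foreground and local background intensity of 6912 spots in both colours on a linear scale, per the file headers, of which 6307 name a gene and 605 are control or blank spots. The files also hold log10 ratios of Cy5 over Cy3, before and after a normalization by the authors whose method is not given in the sources used here. The raw log10 ratio that the authors deposited equals the log10 of the background-subtracted intensities. The value table of the series holds the deposited normalized log10 ratio of the same arrays, in the same direction and scale, with array medians between -0.0425 and 0.0508. All 270 of its columns match a sample, and 0 have none. Log2 values were computed here, since the deposited ratios are on the log10 scale. The scanner, the image software, slide numbers and scan dates are not given in the sources used here, and the error and p-value columns of the files were not used here. The share of gene readings above background (the median of the array's local backgrounds in that colour plus 2 robust SD) ranged from 43.36% to 99.73% over arrays and colours.

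Intensities were corrected with limma's normexp method and an offset of 50, and log ratios were normalized within each array by loess. Control spots and spots that the files mark as bad had weight 0 in the loess, and the marked spots, 8.61% of gene spots, were then left out as missing. The median brightness over background in Cy5 was 317 for marked and 198 for unmarked spots, so marking did not single out dim spots. Each array's ratio was turned to mutant over control. Log2 ratios are on the normexp scale with its offset, which understates changes of dim genes. A gene not measured on an array keeps the value of its other array, which is then named as measured on 1 array. Gene symbols come from a reference gene table of assembly R64 through the systematic names in the files. In all, 5801 of the 6307 gene spots matched it and 5225 have a symbol. No genome build is given in the sources used here, so no coordinates are printed. Genes with near-identical copies (the CUP1 genes, PHO11 and PHO12, THI5 and its copies, histone gene pairs) are uncertain, because a spot can bind both transcripts.

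All 270 arrays entered 1 limma model with a coefficient per group and a gene-wise term for dye orientation, which is the replicate block. Tests were two-sided with moderated variances (prior df 4.99, median residual SD 0.2519 in log2) and Benjamini-Hochberg adjustment over the genes of each strain. A gene was called when its adjusted p was under 0.05 and its change was at least 2-fold. Against limma's own fit, coefficients and standard errors of 400 genes were checked and differed by at most 1.78e-15. The number of calls in both strains of a factor was compared with a sign-flip test of log2(calls + 1) over 51 factors, with 100000 resamples. Means over the 76 overexpression and 51 deletion strains were compared per gene with limma (adjusted p under 0.05 and a difference of at least 1.5-fold). Medians of gene lists were compared between kinds by permuting strains 100000 times, with adjustment over 47 lists.

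Lists of 48 gene groups, 53 pairs of a factor with a list and the expected direction, and 16 pairs of related factors were fixed from textbook knowledge before the data were examined, as were the design, the alternatives and the rule for naming genes. For each factor and list, the median log2 ratio of the list in the factor's own strain was ranked among all strains of its kind, which gives an exact p with a smallest value of 0.0132 for overexpression and 0.0196 for deletion. The number of pairs with rank 1 was tested by reassigning strains to factors 10000 times. The trend of the GCN4 series was tested over all orders of its points. Profiles of strains were compared by Pearson correlation across genes with both own genes left out, and tested by reassigning strains.

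The rule names the own gene of the 5 largest and 5 smallest changes of each kind, up to 3 called list members with the largest change for up to 12 factors per kind, and the 12 genes called in the most strains of each kind. It also names up to 10 genes per direction that differ between kinds, up to 8 list members of the GCN4 series, and the 2 called genes with the largest rise other than the own gene in the 8 strains per kind with the most calls among factors without a list. Genes named outside the rule are said to be chosen after their values were seen.

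The fit was tested on simulated data: 200 of 6307 genes were changed in 40 strains. With equal noise in all strains, 49.5% of 2-fold, 98.6% of 3-fold and 99.8% of 4-fold changes were called, and 0.84% of the calls were false. With the noise of each pair as in the data, these shares were 47.9%, 98.1% and 99.6%, and 13.79% of the calls were false. Among 95 simulated unchanged strains, the median number of false calls was 0 in both settings, but the noisiest pairs gave up to 111, in 11 strains with any. The comparison of 76 with 51 strains called 61% of simulated 1.5-fold and 100% of 2-fold differences.

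Alternatives were median centring in place of loess, the authors' normalized ratios, no background correction, a filter that kept 5181 bright probes (over background in at least 90% of readings), each replicate left out, no replicate block, a 1.5-fold threshold, the spread between strains in place of the spread within pairs, and other summaries of lists and profiles. Further ones were chosen after seeing the data: pairs weighted by their noise, a dye term per kind, marked spots kept, calls required in both arrays, 2 versions of the GCN4 series, and the 55 overexpression strains listed first alone. Software was R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.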

Results

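Transcript levels of budding yeast were measured on 270 spotted arrays of 2 colours, each comparing a mutant strain with its control. The mutants were 76 strains that overexpress a transcription factor, 51 strains that lack one and 8 numbered points of a series labelled with GCN4, the activator of amino acid synthesis genes. Each group had 2 arrays with reversed dyes. Each of the 51 deleted factors was also overexpressed, and 25 factors had an overexpression strain alone. The series text counts 55 overexpression strains. The sample list opens with 55 in alphabetical order, which hold every factor with a deletion, and 21 follow. Whether these are the 55 meant is not stated, and the split was made after seeing the data. The design addresses which genes each factor acts on, by raising it or removing it. Values are log2 ratios of mutant over control, as the mean of 2 arrays with the standard error (SE) of the fit unless 1 array is named.

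Overexpression raised the factor's own transcript in 62 of the 76 strains, with a median log2 ratio of 3.80 over the 74 strains in which it was measured. The largest rises were in YRR1, a regulator of drug resistance (6.55 ± 0.20), SIP4, an activator of gluconeogenesis (6.42 ± 0.16), CAD1, a stress regulator of the YAP family (6.12 ± 0.44, 1 array), HAA1, which acts in weak acid resistance (5.97 ± 0.18), and MET31, a regulator of sulfur metabolism (5.66 ± 0.16). The lowest values were ZAP1 (-0.23 ± 0.11), the activator of zinc uptake genes, GLN3 (-0.13 ± 0.12), BYE1 (-0.09 ± 0.08), OAF1 (-0.07 ± 0.18) and MET4 (-0.07 ± 0.10), and no own gene fell past the test. The BYE1 and MET4 probes were over background in 0 readings of their own strains, so these 2 values do not tell whether the genes were raised. The own gene was also not called in the strains labelled GAT4, MOT3, STP3, PPR1, NDT80, SWI5 and IMP2, and it was missing on both arrays for CRZ1 and YPR015C. These strains are called by their labels throughout, and the overexpression strain of GCN4 is labelled GCN4-A.

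Deletion lowered the factor's own transcript in 8 of the 51 strains, and 17 had an adjusted p under 0.05 with a fall of any size. GIS2 fell most (-4.49 ± 0.25), followed by GCN4 (-3.90 ± 0.45), HAC1, the activator of the unfolded protein response (-1.82 ± 0.22), CST6 (-1.78 ± 0.17) and CUP2, the activator of copper detoxification genes (-1.66 ± 0.12). SKN7 (0.29 ± 0.18, 1 array), MGA1 (0.15 ± 0.20, 1 array), GAT3 (0.09 ± 0.18), GAT4 (0.05 ± 0.12) and HMS1 (0.03 ± 0.19) had the highest values, none past the test. The median was -0.47, with 45 of the 51 below 0, and the control was above background on both arrays for 41. The count rose to 27 with the authors' normalized ratios and to 14 without background correction. Where the probes lie relative to the deleted part is not given in the sources used here, and a probe outside it checks nothing. Deletion strains are named by their labels, whether or not the own gene fell.

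**Figure D1:**
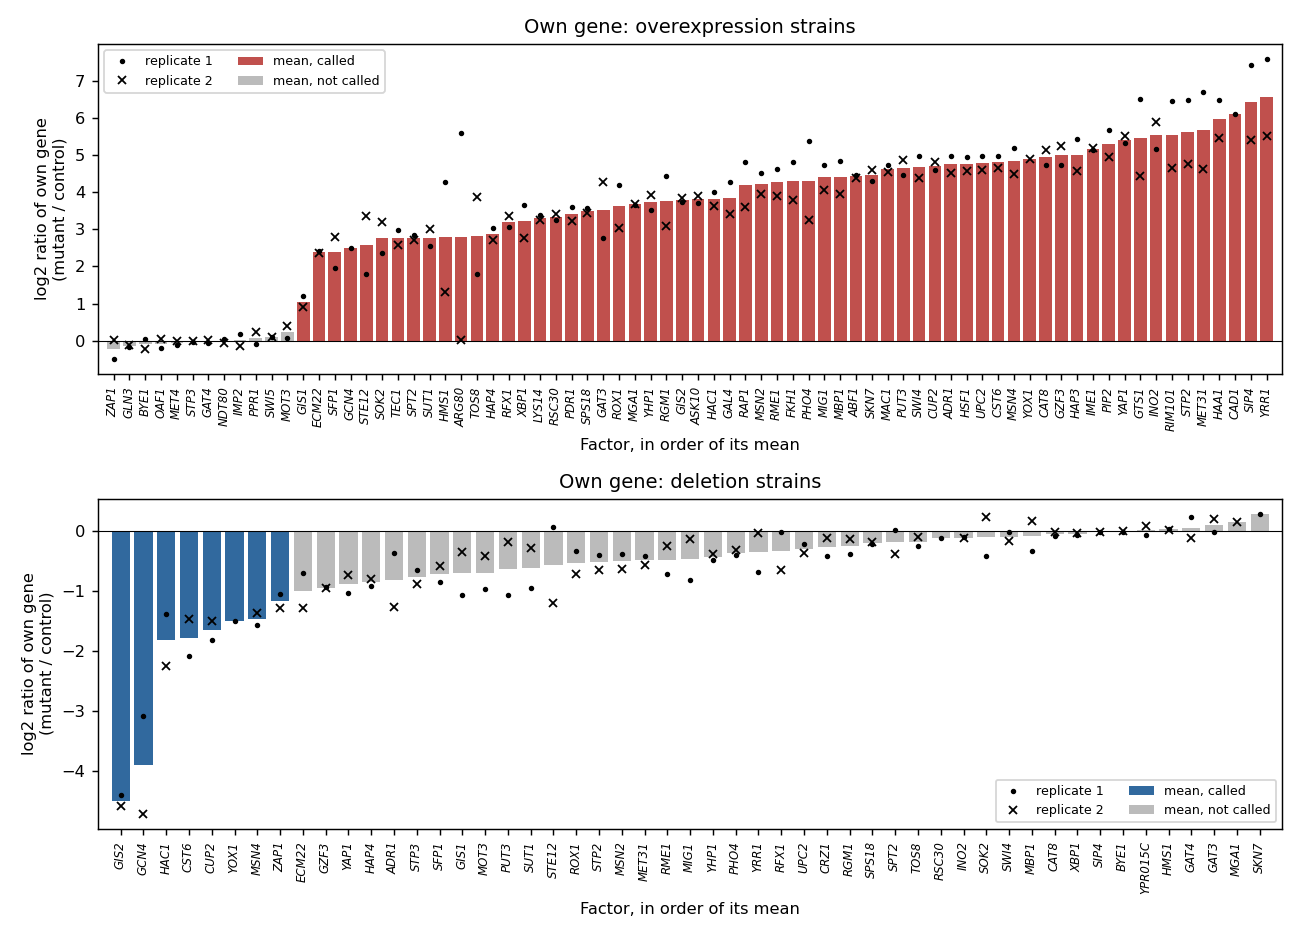
Log2 ratio (mutant over control) of each factor's own gene in its overexpression strain (top) and deletion strain (bottom). Bars are means of the fit, coloured where called, and points and crosses are replicates 1 and 2; 62 overexpressed genes were called higher and 8 deleted genes lower.

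Overexpression changed more genes than deletion of the same factor. The median was 149 called genes in the 55 overexpression strains listed first and 8 in the 21 listed after (two-sided permutation test on log2 of the count plus 1, p = 1e-05, the smallest these resamples can give). The median log2 ratio of the own gene was 3.79 and 3.80 in these sets. Over all strains it was 65.5 called genes per overexpression strain (range 0 to 453) and 6 per deletion strain (range 0 to 245). At least 100 were called in 34 overexpression strains but 6 deletion strains. The medians were 126.5 and 51 with the authors' ratios, and that of overexpression was 99.5 without replicate 2. GAT3 (453 genes), the mating regulator STE12 (442), INO2, the activator of phospholipid synthesis (432), SFP1, a regulator of ribosome synthesis (429), and the strain labelled GCN4-A (371) gave the most calls when overexpressed. The strains labelled as deletions of INO2 (245), SFP1 (189), CST6 (151), MBP1 (124), GIS2 (116) and YHP1 (115) gave the most among deletions. With the authors' ratios the order of deletions was another: INO2 2074, MBP1 886, SFP1 603, STP2 594 and STE12 422, while CST6 had 152, YHP1 174 and GIS2 70. Counts of single overexpression strains also moved with these ratios, such as that of ABF1 from 124 to 646. The arrays of the INO2 deletion were dim, with 46.61% of Cy5 readings over background in replicate 1 and 54.26% (Cy5) and 56.87% (Cy3) in replicate 2. MBP1 was not lower in the strain labelled MBP1 deletion (-0.08 ± 0.18). Within the 51 factors with both strains, overexpression had more calls for 46, fewer for 4 and as many for 1. The median difference was 94 genes (two-sided sign-flip permutation test, p = 1e-05, the smallest these resamples can give).

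Of 9551 calls in overexpression strains 59.29% were higher than the control (50.35% with median centring), and 85.06% changed by at least 1.5-fold the same way in both arrays. Of 1753 calls in deletion strains 52.25% were higher (25.14% with median centring), and 57.5% changed by that much in both arrays. The correlation of the arrays of a pair, across genes, which are not independent replicates, had a median of 0.512 in overexpression and 0.045 in deletion strains. No gene was called by limma in the overexpression strains labelled SWI5 (54 genes at an unadjusted p under 0.05) and BYE1 (212), nor in the deletions of BYE1 (117), GAT4 (197), UPC2 (182), XBP1 (15) and YPR015C (22). Among strains with at least 100 calls, leaving out 1 array moved the count by over 1.5 times for 11 of 34 overexpression and 2 of 6 deletion strains. Without replicate 1 and without replicate 2, the 371 genes of the strain labelled GCN4-A became 188 and 765, the 442 of STE12 764 and 320, the 429 of SFP1 765 and 476, and the 151 of the CST6 deletion 243 and 65. Single arrays decided other counts: the 77 genes of the ADR1 deletion became 400 without replicate 1 and 2 without replicate 2, the 116 of the GIS2 deletion became 227 and 3, the 87 of the YRR1 deletion 430 and 16, and the 174 of the strain labelled PPR1 4 and 521. With pairs weighted by their noise, chosen after seeing the data, the 429 genes of SFP1 overexpression became 143 and the 91 of the ECM22 deletion became 0.

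**Figure D2:**
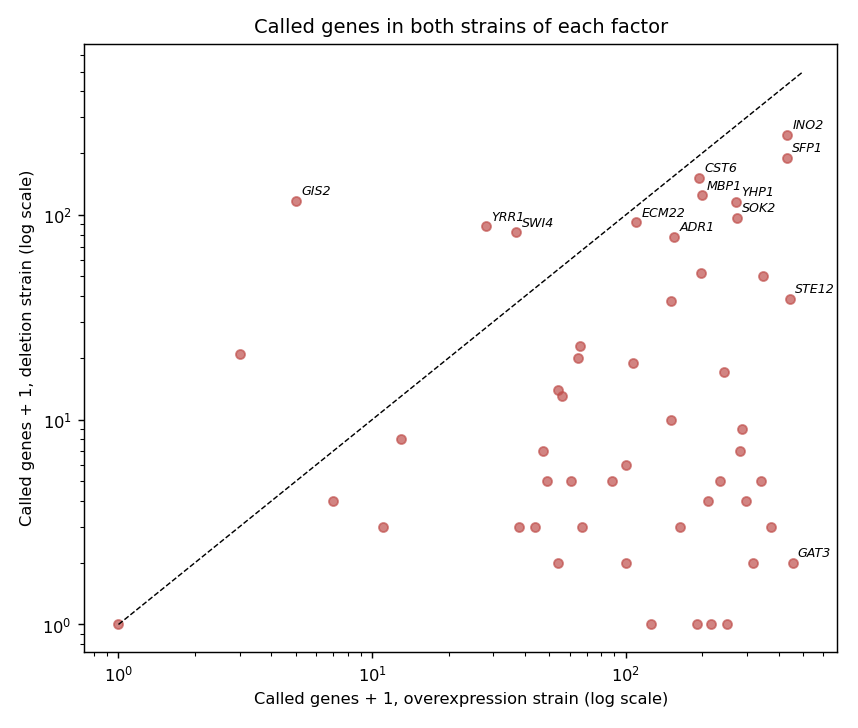
Number of called genes plus 1 in the overexpression strain (x axis, log scale) and the deletion strain (y axis, log scale) of the 51 factors with both, 1 point per factor. The dashed line marks equal numbers, and 46 factors lie below it.

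Known targets of a factor rose in its own overexpression strain for many activators. MSN2, the activator of the general stress response, raised 18 of 22 stress genes, among them the membrane stress protein gene HSP12 (5.20 ± 0.36), the aldehyde dehydrogenase gene ALD3 (4.88 ± 0.29, 1 array) and the small heat shock protein gene HSP26 (3.93 ± 0.23). The strain labelled GCN4-A raised 26 of 30 amino acid synthesis genes, led by ARG1 of arginine synthesis (5.37 ± 0.35), HIS4 of histidine synthesis (4.91 ± 0.25) and LYS1 of lysine synthesis (4.09 ± 0.26), each measured on 1 array. HAP4, the activating subunit of the CCAAT-binding complex, raised 28 of 33 respiration genes, with the cytochrome oxidase gene COX12 (2.46 ± 0.29) and the ATP synthase genes ATP7 (2.14 ± 0.21) and ATP20 (1.97 ± 0.36) at the top.

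ADR1 raised 8 of 10 genes of alcohol use and peroxisomes, including the acetate transporter gene ADY2 (4.08 ± 0.14), the mitochondrial aldehyde dehydrogenase gene ALD4 (3.39 ± 0.26) and the alcohol dehydrogenase gene ADH2 (2.77 ± 0.42, 1 array). INO2 raised 9 of 10 phospholipid synthesis genes, foremost INO1 of inositol synthesis (5.90 ± 0.22), CHO1 of phosphatidylserine synthesis (2.81 ± 0.22) and the fatty acid synthase gene FAS2 (2.45 ± 0.20). In the strain labelled ZAP1, whose own gene was not raised, 7 of 12 zinc-responsive genes rose, among them VEL1 (6.52 ± 0.26, 1 array), the cell surface protein gene ZPS1 (5.52 ± 0.24) and the zinc transporter gene ZRT1 (4.90 ± 0.24). PHO4 raised 9 of 17 phosphate genes, with the transporter genes PHO84 (4.35 ± 0.25) and PHO89 (4.04 ± 0.21) and the acid phosphatase gene PHO12 (3.82 ± 0.25) highest. In the strain labelled CRZ1, 7 of 9 calcineurin-dependent genes rose, including the protein kinase gene CMK2 (3.21 ± 0.21), PUN1 (2.41 ± 0.27, 1 array) and the protease gene YPS1 (2.31 ± 0.16).

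SUT1 raised 5 of 8 anaerobic cell wall and sterol uptake genes, led by the sterol transporter gene AUS1 (3.88 ± 0.16) and the mannoprotein genes TIR4 (3.26 ± 0.11) and TIR2 (2.75 ± 0.33). UPC2, an activator of sterol synthesis, raised 5 of 22 ergosterol genes, namely the squalene synthase gene ERG9 (2.59 ± 0.20), ERG25 (1.79 ± 0.27), ERG6 (1.33 ± 0.15) and 2 others. STE12 raised 13 of 20 mating genes, including FIG1 (3.83 ± 0.17), ASG7 (3.59 ± 0.20) and the agglutinin gene AGA1 (3.54 ± 0.23, 1 array), and SOK2 overexpression had a higher median for that list than STE12 (1.66). HSF1, the heat shock factor, raised 15 of 17 chaperone genes with a list median of 1.46, next to 1.75 in ABF1 overexpression. With median centring these medians were 1.17 and 1.11, in the reverse order. The same counts held when adjusted over the list alone.

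Among 53 pairs of a factor and a list, the own strain had the most extreme median of the 76 in the expected direction for 11, against 0.697 by chance (permutation test, p = 1e-04, the smallest the 10000 draws can give), and was among the 3 most extreme for 22. Within the 55 strains listed first it was 12 (permutation p = 1e-04). The list medians of these 11 were 2.48 (MSN2, next strain 1.07), 2.30 (ADR1), 2.13 (SUT1), 2.05 (GCN4-A), 1.63 (HAP4), 1.56 (INO2), 1.41 (CRZ1), 1.15 (ZAP1), 1.08 (PHO4), 0.68 (UPC2) and -0.48 for the repressor YOX1 on genes of the M/G1 boundary, none of which was called. No single pair passed adjustment over the 53 (exact p = 0.0132, adjusted p = 0.0634 for each of the 11). The exact p of a first rank is the smallest possible, so no pair could pass this adjustment on its own, however extreme. MET31 ranked 75 for sulfur genes, PIP2 65 and OAF1 60 for beta oxidation genes, CAD1 62 for oxidative stress genes, GLN3 67 for nitrogen genes, MBP1 58 for its cell cycle targets and RAP1 57 for ribosomal protein genes.

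**Figure D3:**
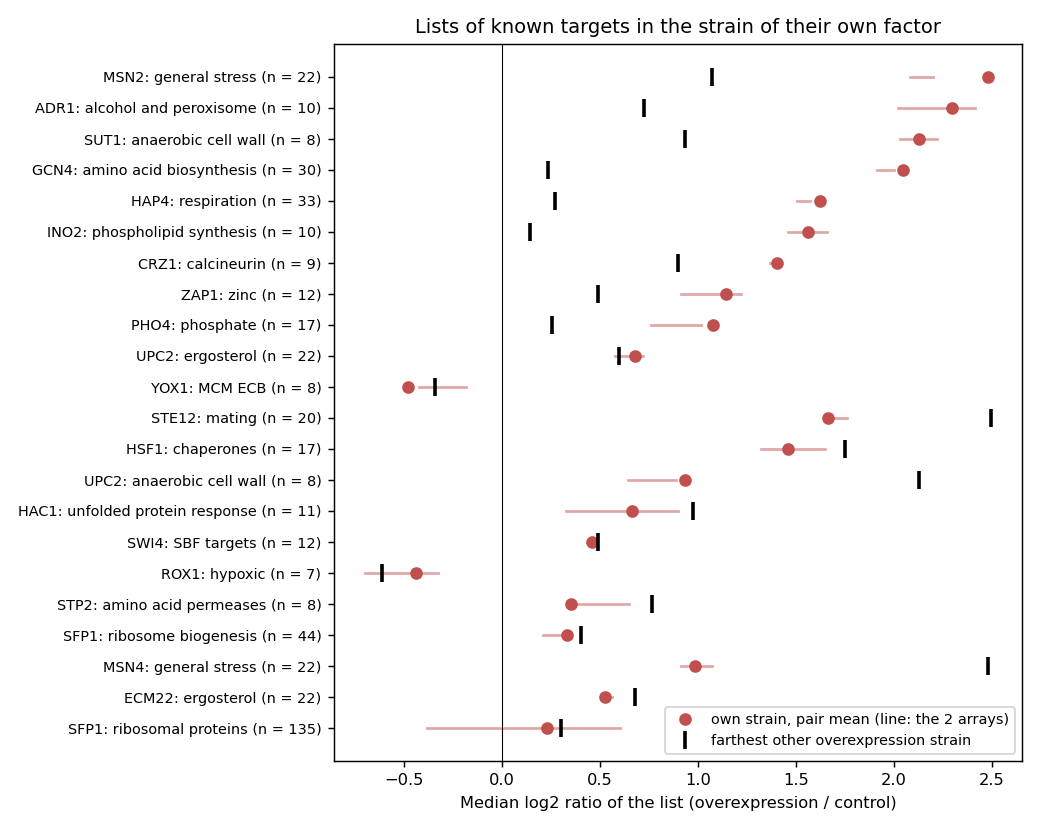
Median log2 ratio (overexpression over control) of lists of known targets in the strain of their own factor (circles) for the 22 pairs among the 3 most extreme, with n the list members measured. Lines join the medians of the 2 arrays taken alone, and black ticks mark the most extreme other strain, which was passed by 11 circles.

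Known targets were also called in deletion strains. The deletion of RFX1, a repressor of ribonucleotide reductase genes, raised 2 of 4 of them, RNR4 (2.77 ± 0.22) and, somewhat less, RNR2. The deletion of ROX1, the repressor of hypoxic genes, raised 2 of 5, the heme synthesis gene HEM13 (2.34 ± 0.13) and ANB1 (1.15 ± 0.24), a hypoxic translation factor gene. The STE12 deletion lowered 5 of 20 mating genes, with AGA1 lowest, then the cell fusion gene FUS1 (-1.83 ± 0.18) and the signalling gene SST2 (-1.78 ± 0.23, 1 array), and the PHO4 deletion lowered 7 of 15 phosphate genes, with PHO84 (-4.19 ± 0.25), SPL2 (-3.01 ± 0.27) and PHO12 (-1.97 ± 0.25) lowest. The INO2 deletion lowered 1 of 12 phospholipid genes, the inositol transporter gene ITR1 (-1.28 ± 0.25). The median of that list was -0.31 here, but -1.38 with the authors' ratios and -0.76 with median centring. The SFP1 deletion lowered 4 of 122 ribosomal protein genes but raised 1 of 37 ribosome synthesis genes, ERB1 (1.14 ± 0.21), against the expected direction. The medians of these 2 lists were -0.19 and -0.18, both in the expected direction, and -1.01 and -0.24 with median centring. That of the ribosomal protein genes was -0.46 in replicate 1 and 0.0044 in replicate 2 here, so it depends on the array and the normalization. The ZAP1 deletion lowered 4 of 13 zinc genes. Adjusted over the list alone, that count was 5 and the others here were the same.

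The own strain had the most extreme median of the 51 for 3 of 34 pairs (RFX1 at 1.65, ROX1 at 0.56 and STE12 at -0.42), against 0.667 by chance (permutation test, p = 0.026), and was among the 3 most extreme for 10. This count was 2 with dim probes filtered out (permutation p = 0.14) and 2 without replicate 2 (permutation p = 0.144), both not past 0.05, and between 5 and 8 under 5 other settings. No single pair passed adjustment over the 34 (exact p = 0.0196, adjusted p = 0.167), and again none could on its own. With the authors' ratios the medians were 2.58 for RFX1, 0.77 for ROX1 and -1.36 for STE12. That of STE12 was -0.21 and -0.70 in replicates 1 and 2 here.

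For factors without a fixed list, the largest rises other than the own gene were taken one by one, with no test of a group of genes. GAT3 overexpression raised the spore wall genes DIT1 (6.67 ± 0.23) and DIT2 (4.87 ± 0.15), and the strain labelled GAT4 raised DIT1 (4.79 ± 0.23) and HSP26 (4.34 ± 0.23). RME1, a repressor of meiosis, raised HSP26 (5.68 ± 0.23) and the gluconeogenic gene FBP1 (4.41 ± 0.20), GIS1 raised CPP3 (5.03 ± 0.17) and HSP26 (4.50 ± 0.23), and CST6 raised HSP12 (3.84 ± 0.36) and the thiamine synthesis gene THI5 (3.61 ± 0.22, 1 array, with near-identical copies). SOK2 raised the mating genes FIG1 (5.95 ± 0.17) and PRM6 (4.33 ± 0.12), HMS1 raised the pyruvate decarboxylase gene PDC6 (3.99 ± 0.23) and JLP1 of sulfonate use (3.72 ± 0.09), and the strain labelled YPR015C raised the ribonucleotide reductase genes RNR2 (2.82 ± 0.21) and RNR3 (2.65 ± 0.12).

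Among deletions, the stress genes ALD3 and HSP12 rose in the strain labelled SOK2 deletion (4.24 ± 0.20 and 4.19 ± 0.36) and in the CST6 deletion (2.91 ± 0.20 and 3.49 ± 0.36). CHA1, a serine and threonine deaminase gene, rose in the GIS2 deletion (1.49 ± 0.26) and in the strain labelled HMS1 deletion (1.63 ± 0.26), where the copper transporter gene CTR1 rose too (1.18 ± 0.14). The STP3 deletion raised the siderophore transporter gene SIT1 (1.41 ± 0.16) and PSR2 (1.19 ± 0.25, 1 array, not called with pairs weighted by their noise), and the strain labelled SPT2 deletion raised YGP1 (1.04 ± 0.20), a secreted stress glycoprotein gene. Other calls rested on 1 array: the a-factor genes MFA2 and MFA1 in the SKN7 deletion were at 3.02 and 2.55 in replicate 2 and at 0.06 and -0.03 in replicate 1, the serine synthesis gene SER3 in the SPT2 deletion was at 3.54 and 0.19, and the profilin gene PFY1 (2.41 ± 0.41) and the histone gene HHT2 (2.26 ± 0.55) in the TOS8 deletion were measured on 1 array.

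A small set of genes changed in many overexpression strains. INO1 was called in 41 of the 76 strains, lower in 38 and higher in 3. Lower calls also prevailed for the flavohemoglobin gene YHB1 (25 of 29), the cytochrome c gene CYC1 (27 of 28) and the mitochondrial tRNA synthetase gene MSR1 (24 of 28). Higher calls prevailed for the stress genes HSP26 (30 of 31), HSP12 (27 of 33) and DDR48 (17 of 22) and for the cell wall gene SPI1 (24 of 24), whereas the carbonic anhydrase gene NCE103 (18 higher of 34), YGP1 (13 of 27) and the cell wall mannoprotein genes CWP1 (13 of 24) and TIP1 (12 of 23) went both ways. Of the 2844 genes called in at least 1 overexpression strain, 231 were called in at least 10 and 19 in at least 20.

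Among the 51 deletion strains, the zinc-responsive genes ZPS1 (16 lower of 22) and ZRT1 (10 lower of 15) were called most often together with CHA1 (13 higher of 15). PHO84 went both ways (7 higher and 7 lower). The ribosomal RNA processing gene RRP5 was higher in 10 of 10. The acid phosphatase genes PHO11 (7 lower of 8) and PHO12 (6 lower of 7) and the alcohol dehydrogenase gene ADH4 (6 lower of 7) followed, then YGP1 (5 higher of 7), HSP12 (5 higher of 6), DDR48 (4 higher of 6) and SPL2 (3 higher of 6). With the authors' ratios RRP5 was called higher in 20 deletion strains, and ADH4 was called lower in 1 and higher in 0. Deletion strains had 1040 genes called at least in 1 strain, 5 in at least 10 and 1 in at least 20.

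**Figure D4:**
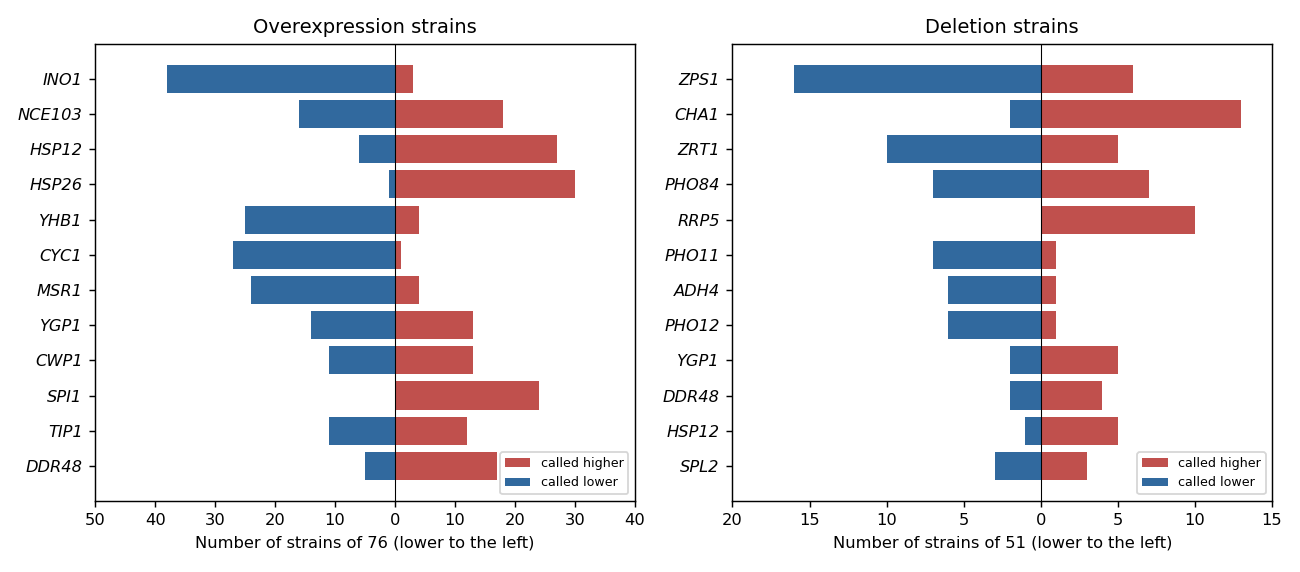
Number of strains in which a gene was called higher (right) or lower (left), for the 12 genes called in the most overexpression strains (left panel, of 76) and deletion strains (right panel, of 51). INO1 was called lower in 38 overexpression strains and ZPS1 lower in 16 deletion strains.

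Compared between kinds of strain, 11 genes differed in their mean log2 ratio by at least 1.5-fold. The number was 41 with the authors' ratios, 38 with the 51 factors paired, 19 without replicate 1, 17 with median centring, and 39 with the 55 overexpression strains listed first but 2 with the 21 others. HSP26 was higher in overexpression than in deletion strains (1.18 against 0.11, difference 1.07 ± 0.25, limma adjusted p = 0.00165), as was ZPS1 (0.25 against -0.55, difference 0.80 ± 0.21, adjusted p = 0.00532). Lower in overexpression strains were INO1 (difference -1.01 ± 0.20), CYC1 (-0.80 ± 0.15), CHA1 (-0.72 ± 0.14), RRP5 (-0.70 ± 0.08, measured in 61 and 38 strains), SFG1 (-0.66 ± 0.10), the spindle checkpoint gene IBD2 (-0.59 ± 0.08) and the tRNA methyltransferase gene GCD10 (-0.59 ± 0.06), with adjusted p between 1.1e-13 and 0.00022. The other 2 were open reading frames without a name, YFL015C (-1.21 ± 0.15, adjusted p = 1.6e-09) and YDR133C (-0.61 ± 0.18, adjusted p = 0.0175). With the authors' ratios RRP5 (0.07 against 1.80) and YFL015C (-1.86 against 0.14) lay farther apart. INO1 was below 0 in 67 of 76 overexpression strains and 22 of 48 deletion strains, CYC1 in 59 of 76 and 26 of 51. In the 21 strains listed after, the means of HSP26 (0.10), INO1 (-0.14), CYC1 (0.01) and SFG1 (0.01) were near 0, while those of YFL015C (-0.94), GCD10 (-0.71) and IBD2 (-0.53) were not.

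By list, 17 of 47 differed between kinds (permutation test, adjusted over the lists), 22 with the 55 strains listed first and 0 with the 21 others. Lower in overexpression strains were the medians of phospholipid synthesis (difference -0.24, adjusted p = 0.00047), histone (-0.39, 0.000564, with near-identical copies), early G1 (-0.22, 0.000564), mitotic CLB2 cluster (-0.12, 0.000627), SBF target (-0.21, 0.00159), respiration (-0.26, 0.00169) and MBF target genes (-0.06, 0.0123). Higher were those of oxidative stress (0.09, 0.00047), proteasome (0.10, 0.000564), unfolded protein response (0.10, 0.000806), chaperone (0.20, 0.00169), alpha mating type (0.14, 0.00436), cell wall integrity (0.12, 0.00604), calcineurin (0.11, 0.00604), beta oxidation (0.06, 0.03), phosphate (0.09, 0.0471) and alcohol and peroxisome genes (0.09, 0.0485). Histone medians had an SD of 0.56 over overexpression and 0.39 over deletion strains, and were below 0 in 59 of 76 and 26 of 51. The kinds also differ in their control strain, which these tests cannot separate.

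In the GCN4 series, amino acid synthesis genes rose from point 30 on. The unit of the numbers is not given in the labels. Called higher were 0 list members at point 0, 1 at 12.5, 12 at 30, 12 at 45, 21 at 60, 15 at 120, 17 at 180 and 16 at 300, of 33 or 34 measured. Adjusted over the list alone, the counts were 0, 1, 13, 13, 22, 15, 17 and 17. HIS5 (2.43 ± 0.23), HIS4 (2.01 ± 0.17) and CPA1 (1.82 ± 0.26) were highest at 60, ARG1 (2.19 ± 0.25), ARG3 (1.97 ± 0.18) and ARG4 (1.62 ± 0.17) at 30, and LYS1 (1.60 ± 0.18) at 300. With the authors' ratios GCN4 itself was called at 180 (limma adjusted p = 0.0209) and 300 (0.0024), but otherwise it was called at none of the 8 points, with log2 ratios of -0.25, -0.16, 0.11, 0.28, -0.17, 0.66, 1.20 and 1.39 in their order (limma adjusted p = 0.23 at 180 and 0.053 at 300). The GCN4 values at 45 and 120 were each measured on 1 array.

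The list median was 0.01, 0.13, 0.77, 0.85, 1.26, 0.94, 1.03 and 1.02 over the 8 points, and all called genes numbered 0, 5, 32, 25, 59, 39, 64 and 79, of which 1 at 60 and 1 at 300 were lower. Single arrays moved some of these: without replicate 1 and without replicate 2, point 12.5 had 0 and 6, 30 had 54 and 11, 45 had 21 and 16, 60 had 114 and 14, 120 had 25 and 49, and 180 had 29 and 66. The peak of the list median at 60 rests on replicate 2 (medians of 0.83 and 1.53 in replicates 1 and 2). At point 0, 113 genes had an unadjusted p under 0.05. The median rose with the number (rho 0.833, exact p = 0.0154 over all orders of the points), but not past 0.05 by the mean of the list (rho 0.69, exact p = 0.0694), while r was 0.564 (exact p = 0.118) and 0.716 without points 180 and 300, in a family of 1 trend. In the separate strain labelled GCN4-A the median was 2.05, with 248 genes higher and 123 lower. In the GCN4 deletion it was -0.16, with 2 genes lower and none of the 31 measured list members called (ARG1 -0.91).

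Replicate 1 of point 0 and replicate 2 of point 12.5 held identical brightness at 90.41% of 6912 spots in Cy5 and 90.34% in Cy3, against at most 4.56% and 3.15% in the other of 36315 pairs of arrays, so they are 1 scan under 2 labels of opposite dye orientation, of which at most 1 can hold. Without that scan the medians of points 0 and 12.5 were 0.20 and 0.19, with 5 and 9 called genes, and rho was 0.81 (exact p = 0.0218). With both points left out, rho was 0.60 (exact p = 0.242) and r 0.242 (exact p = 0.613), so the trend rests on points 0 and 12.5. Both alternatives were chosen after seeing the data.

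**Figure D5:**
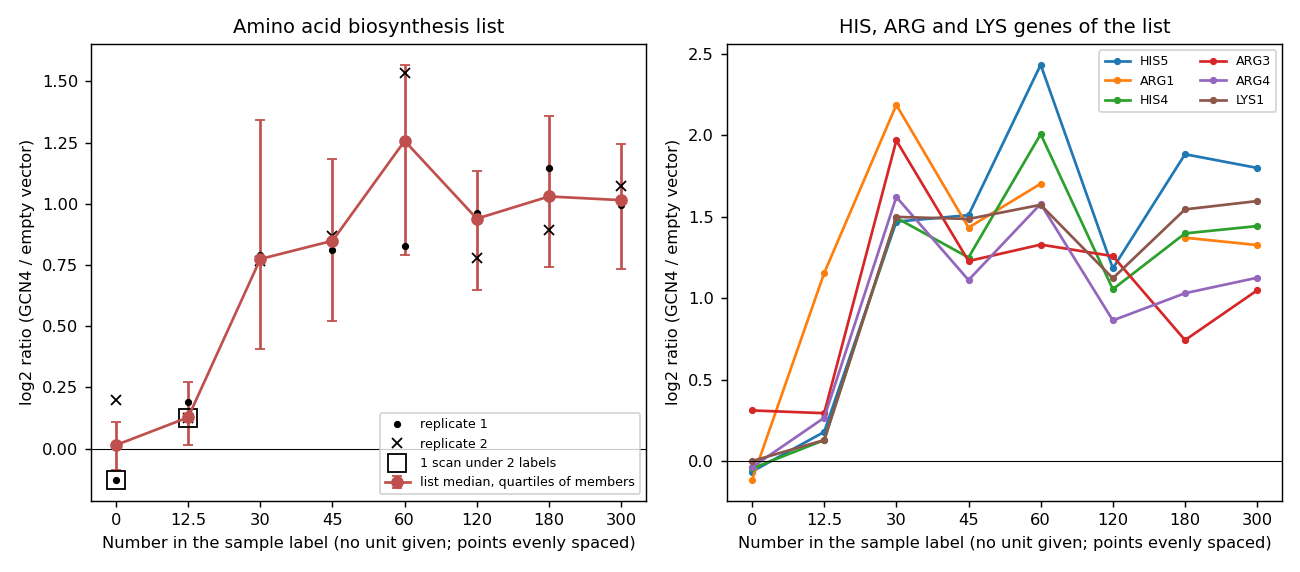
Left, median log2 ratio (GCN4 over empty vector) of the amino acid synthesis list at the 8 points with quartiles of its members and the medians of both arrays, squares marking the scan that stands under 2 labels. Right, 6 HIS, ARG and LYS genes of the list, with a gap where a point was not measured; the list median was 0.01 at point 0 and 1.26 at 60.

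Of the genes called in both strains of a factor, some changed in opposite directions and others the same way, and whole profiles were not opposed. STE12 overexpression and deletion shared 26 called genes, all changed in opposite directions, SFP1 45 (41 opposite), PHO4 7 (7 opposite) and the strains labelled ZAP1 3 (3 opposite), while 69 of the 72 genes shared by both INO2 strains, the deletion on dim arrays, and 24 of 26 of CST6 changed the same way. Few shared genes were also opposite for STP2 (1 of 8), the strains labelled MBP1 (3 of 12) and YHP1 (5 of 14). Over the 51 factors, 252 called genes were shared, 116 of them opposite and the larger part the same way. Independent lists gave 33.27 opposite and 29.23 same. Such lists make no allowance for genes called in many strains, so they may understate both numbers. The correlation of both profiles across genes, which are not independent replicates, had a median of -0.0139 (permutation test over strains, p = 0.27; 95% of reassignments between -0.0298 and 0.0334), was lowest for ZAP1 (-0.295) and highest for INO2 (0.31), and lay below 0 for 28 factors. It was -0.0205 with the authors' ratios (p = 0.0378) and 0.00515 without replicate 1.

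Overexpression of some related factors changed the same genes. The homeodomain repressors YHP1 and YOX1 changed 161 genes the same way (5.51 from independent lists; r across genes 0.855), GAT3 and the strain labelled GAT4 177 (9.33; 0.725), the sterol regulators UPC2 and ECM22 60 (2.75; 0.492) and the stress regulators MSN2 and MSN4 25 (1.07; 0.39), and in each of these pairs the partner was the closest of the 75 other overexpression strains. Some others shared few, here with the number from independent lists and r: the YAP family members YAP1 and CAD1 0 (0.021, 0.0029), HAP4 and HAP3 1 (0.075, -0.0102) and STE12 and TEC1 0 (0.277, 0.195). CAD1, HAP3 and TEC1 are among the 21 strains listed after, with a median of 8 calls. These 3 pairs thus had few calls to share and do not tell whether the factors act on different genes. RAP1 and SFP1 shared 20 (4.22 from independent lists, r 0.105), and the strains labelled MET4 and MET31 shared 19 (1.86, r -0.0009). Their partners ranked only 51 and 55 of 75. Independent lists make no allowance for genes called in many strains (231 in at least 10), so they may understate the overlap of unrelated strains. The median r of 16 fixed pairs was 0.13 (permutation test, p = 0.166), against 0.0787 over all pairs of overexpression strains. Among the 55 strains listed first it was 0.145 for 10 pairs, against 0.129 over all pairs (permutation p = 0.732). Part of any overlap may come from shared control RNA, on which the labels are silent.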

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

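The tests of pair noise, of brightness and of other splits of the strains were chosen only after the results they test were seen. The median difference of 94 called genes between the overexpression and the deletion strain of a factor is listed here because the effects of the 2 kinds of strain differ by a permutation test. The tables argue against 2 technical explanations as the whole cause. Overexpression pairs were not less noisy, with a median ratio of their noise to that of the deletion pairs of 1.11 (sign-flip permutation test, p = 0.0379). Brighter arrays do not account for the difference, which was 89 with dim probes filtered out. Centring of each gene within its kind removes a response equal in all strains of a kind, and left 59. The medians were then 58 and 5 (sign-flip permutation p = 1e-05, the smallest the resamples can give). More calls in overexpression remained for 46 factors. Centring used the mean over all strains of a kind, including the 21 overexpression strains not among the 55 listed first. In these 21, INO1 (-0.14 against -1.24 in the 55) and HSP26 (0.10 against 1.60) were smaller in size. GCD10 (-0.71 against -0.55) and IBD2 (-0.53 against -0.58) were alike. Part of a response shared by the 55 alone can thus remain in the 59. Centring therefore cannot decide on such a response, as an unequal control may give. The control type changes with the kind of strain. Controls that differ between strains or sets of strains and a stronger effect of raising a factor than of removing it therefore cannot be told apart. The stronger effect is an untested hypothesis. All 51 overexpression strains compared here are among the 55 listed first (median 149 calls), while the 21 others had a median of 8. Whatever sets the 55 apart, which was not tested, can therefore not be separated from the difference either.

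The 11 genes whose mean log2 ratio differs between overexpression and deletion strains are listed because limma tested that difference itself. Of 100 splits of the strains into 76 and 51, the real one gave 11 genes and the highest other gave 0, which argues against a random division of independent strains. Strains that share controls or a place in the sample list are not independent, so these splits cannot exclude such groups as the source. The count of splits with as many genes was 1, the real one. The 17 gene lists whose medians differ between the kinds are listed for the same reason, by a permutation test with adjustment over the lists, and whether their control strains or the factors set them apart was not tested. The 21 overexpression strains not among the 55 listed first, which are fewer, gave 2 genes and 0 lists against the deletions. The differences of the 17 lists were smaller in size with the 21 than with the 55. For the genes, the means of HSP26, INO1, CYC1, SFG1, ZPS1, CHA1 and YDR133C were smaller in size in the 21. Those of RRP5 (-0.01 in both), GCD10 (-0.71 against -0.55) and IBD2 (-0.53 against -0.58) were alike, and YFL015C was at -0.94 against -1.37. Why the 21 differ from the 55 was not tested.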

How the results depend on the processing

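Weighting pairs by their noise, a dye term per kind, keeping marked spots, asking for both arrays, the 55 overexpression strains listed first alone and the 2 versions of the GCN4 series are tests chosen only after the data were seen; the other alternatives were planned. Comparing each result with each of its alternatives, 113 values were counted as the same and 26 counts moved. Of the rest, 4 results were no longer past their threshold, 1 passed it newly and 1 turned. A count was the same if it moved by at most 1.5 times and, where tested, stayed on its side of the threshold. The GCN4 trend and the r values were the same if sign and side of the threshold held, whatever their size. The r of related factors is thus among the 113 although it fell from 0.13 to 0.0397 with genes centred. Own genes called in overexpression strains ranged from 52 to 64, known targets ranked first in overexpression from 11 to 13, lists that differ between kinds from 17 to 23, and the r of related factors from 0.0397 to 0.166 (permutation p from 0.0592). With the 55 strains listed first alone, the median of overexpression was 149 and genes between kinds numbered 39. The difference of 94 calls kept a permutation p of 1e-05, the smallest possible, under its 13 alternatives. With the authors' normalized ratios, own genes lowered by deletion numbered 27 (8 as reported), median calls were 126.5 for overexpression and 51 for deletion, known targets in deletions 5, genes that differ between kinds 41, and the r of both profiles of a factor -0.0205 (permutation p = 0.0378). With 1.5-fold in place of 2-fold, the counts were 17 own genes in deletions, medians of 215.5 and 17, a difference of 264 and 204 genes at GCN4 point 300, since a lower threshold admits more. Without background correction there were 14 own genes and 6 known targets in deletions, and with median centring 6 known targets and 17 genes between kinds. The spread between strains gave a median of 40 for overexpression and a difference of 52, marked spots kept gave 10 for deletion, and the demand on both arrays 3, being stricter. Known targets in deletions numbered 2 with dim probes filtered out (permutation p = 0.14) and 8 by the mean of a list. The GCN4 trend was 0.60 without points 0 and 12.5 (exact p = 0.242) and 0.69 by the mean (exact p = 0.0694). Genes between kinds numbered 920 with no fold threshold, which admits small differences, and 38 with the 51 factors paired. Leaving out each replicate, with lone arrays assumed to vary like the other groups, gave medians of 60.5 to 99.5 for overexpression, 2 (permutation p = 0.144) to 6 known targets in deletions, 12 to 19 genes between kinds, a trend of 0.786 to 0.976, and r from -0.00884 to 0.00515, which turned its sign without replicate 1 and had p = 0.27 by permutation as reported. Where no reason is given, the cause was not tested. Without the replicate block, median calls were 64.5 and 6, their difference 84, own genes 62 and 8 and GCN4 point 300 had 79, none of them moved by over 1.5 times, and the difference kept its permutation p; the other results were not run without it. A block for slides or scan dates was not run, because the labels give neither. Signal over background reached 43.36% to 99.73% of readings per array, and changes of dim genes are understated.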

Other observations

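The lists and strains of the next 2 paragraphs were chosen after their values were seen, as were RSC30, MED6 and SOK2 further on, the tests of a swap and of a wrong label for the strain labelled MET4, and the split by place in the sample list. SUT1 overexpression had the lowest median of respiration genes of the 76 overexpression strains (-2.24, 30 of 33 measured list members called lower) and the highest of hypoxic genes (1.17, 5 of 7 higher). CUP2 overexpression was lowest for glycolysis (-2.35, 12 of 15 lower), SBF targets (-1.59, 8 of 10) and early G1 genes (-1.59, 7 of 13), and MIG1 overexpression was highest for glycolysis (1.74, 10 higher). XBP1 overexpression was highest for gluconeogenesis (1.89, 7 of 10 higher), SPS18 for the unfolded protein response (0.98, 5 of 11) and the strain labelled YPR015C for ribonucleotide reductase genes (2.63, 3 of 4). With the authors' ratios HAC1 overexpression passed SPS18 for the unfolded protein response (1.22 against 1.085). Lowest for phospholipid synthesis was GAT3 overexpression (-1.30, 8 of 12 lower). HSF1 overexpression was highest for copper detoxification genes (5.54), a list with near-identical copies.

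Genes that mark the a mating type were highest in STE12 overexpression (2.04, 6 of 7 called higher) and lowest in TOS8 overexpression (-1.78, 5 of 7 lower). Among deletions they were highest in the YHP1 deletion (2.88, 6 of 6 higher) and lowest in the STE12 deletion (-2.54, 5 of 7 lower), while alpha-type genes were highest in STE12 overexpression too (3.05, 4 of 4 higher). The SFP1 deletion gave the highest deletion median of respiration genes (0.86, 13 higher), the strain labelled SOK2 deletion that of general stress genes (1.87, 16 of 22), and the CST6 deletion those of weak acid (1.23, 3 of 6) and arginine genes (1.12, 3 of 6).

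In the strain labelled MET4 overexpression MET4 was at -0.07 ± 0.10, while RSC30 (3.40) and MED6 (2.28) stood close to their values in the RSC30 strain (3.34 and 2.41); RSC30 was called higher in 10 overexpression strains (up to 2.05 in the others) and MED6 in 2. The value 3.34 argues against swapped labels of the 2 strains, and profiles argue against the RSC30 strain under a wrong label, since the RSC30 strain ranked 24 of 75 by correlation with it (r 0.157, against 0.66 for CUP2 overexpression, with 5 calls shared of 282 and 10). A MET4 probe that gives no signal cannot be told apart from missing overexpression: the probe was over background in 53.7% of 536 readings of other arrays (95% interval 49.5 to 57.9) and in 0 of 4 in this strain, and its highest log2 ratio in any strain was 0.17. The sulfur gene CYS3, chosen after its value was seen, was at 1.43 (limma adjusted p = 2.59e-07) against 0.33 in the RSC30 strain, and the sulfur list had a median of 0.10 (rank 8 of 76, 2 members called higher) and 0.61 with the authors' ratios, which leaves open whether MET4 was raised. Also chosen after their values were seen, CPR2 was at 1.31 in the strain labelled MET4 (limma adjusted p = 6.28e-06) and CUP1-1 at 1.19 (0.0492). There CUP1-2 was at 1.19 (0.0562) and YHR054C at 0.93 (0.000341). In the RSC30 strain these 4 genes were at 0.14, -0.52 (1 array), -0.33 and 1.05, and only the last was called. Another plasmid in the strain labelled MET4 was not tested, and no biological explanation was tested.

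Early G1 genes were lower in many overexpression strains. Slower growth of those strains may account for this, but across the 76 strains their median had no correlation past the test with that of the general stress list (rho -0.0952, permutation p = 0.412), while it rose with ribosome biogenesis genes (rho 0.265, p = 0.0214, adjusted over 3 lists 0.0321) and histone genes (rho 0.519, p = 1e-05, the smallest these permutations can give, adjusted p = 3e-05). The r values were -0.106, 0.32 and 0.681, and -0.132, 0.212 and 0.635 without the 2 farthest strains. Spearman's rho within the 55 strains listed first was -0.0661, 0.297 and 0.581 (permutation p = 0.63, 0.0275 and 1e-05) and within the 21 others 0.0935, -0.0805 and 0.21 (p = 0.685, 0.73 and 0.358). These lists point different ways, so slower growth and an effect of the factors on the cell cycle cannot be told apart, and no growth rate was used here.

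The nearest measured gene on each side of a changed factor was rarely called. Genes beyond these nearest ones were not tested. In overexpression 1 of 152 nearest neighbours was called higher (1.83 with strains reassigned, permutation p = 0.842), and in deletion 0 of 102 were called by limma (0.608, permutation p = 1). In the strain labelled MBP1 deletion, MBP1 was at -0.08 ± 0.18 and SOK2 at -1.43 ± 0.29 (limma adjusted p = 0.000103), and in the strain labelled SOK2 deletion SOK2 was at -0.10 and MBP1 at 0.02.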
